A study of Mus musculus with 16 samples.

How the data were processed

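RNA sequencing was done on 16 small cell lung cancers from mice in which deletion of Trp53 and Rb1 started tumor formation. CRISPR mutated p107 (gene Rbl1) in 8 tumors and p130 (gene Rbl2) in the other 8. Per the labels' protocols, the tumors were dissected from lungs and flash-frozen, total RNA was taken, and libraries were made with a KAPA mRNA kit. The number in each tumor's title was read as its mouse, which gives 4 mice for p107 and 3 for p130. Tumors are named by their titles, in which sgp107 or sgp130 is the guide RNA, the number the mouse and T1 to T5 the tumor. The labels call the tumors biological replicates. Each mouse carried 1 genotype, so the mouse could not enter the fit as a fixed block.

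The authors deposited a table of estimated counts per gene and tumor, with 23224 gene rows. RSEM 1.2.12, Bowtie 1.0.1 and the mouse build mm9 are named in the submitters' processing notes. The gene annotation and the strand setting are not given in the sources used here. Without a known strand setting, overlapping and antisense genes cannot be told apart, and RSEM divides reads among near-identical genes, which concerns Y-linked genes with X-linked copies. Between 42.1% and 54.6% of the estimated counts of a tumor were not whole numbers. A second deposited table holds a normalized signal for 21523 of the rows. From its values, each column is the estimated count column times a constant that sets the upper quartile to 1000. It leaves out 1701 rows by a rule not given in the sources used here. These rows hold 2.62% to 4.22% of the counts of a tumor and include Xist, Egfl6 and 729 rows named as microRNA or small nucleolar RNA genes. The normalized table served only as an alternative. Another 25 rows carry dates in place of gene symbols and stayed unnamed. Genes are given by the symbols in the tables. No coordinates are given, since the reference annotation used here is of another build than the counts, and only its gene order was used.

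Estimated counts were rounded to whole numbers. edgeR 4.0.16 in R 4.3.3 tested p107 minus p130 tumors with TMM factors, filterByExpr and the robust quasi-likelihood F test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Levels are CPM, counts scaled to library size, with TMM factors. The standard error of a log2 fold change is its size divided by the root of F, and fold changes carry 95% intervals. For single genes, an exact two-sided permutation test compared mean log2(CPM + 1) over all 12870 splits of the 16 tumors, and over the 35 splits of the 7 mice, whose smallest p is 0.0286.

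Before the data were examined, the main tests, most alternatives, 35 gene lists with 704 entries and the rule for naming genes were fixed. Of the list entries, 9 had no symbol in the tables. The lists cover states and pathways of small cell lung cancer and markers of other cell types in lung or liver. Of these, 33 were tested with camera on voom values (limma 3.58.1), with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Members counted as higher or lower are from edgeR and mean log2 fold changes of lists from voom, unless said otherwise. The lists of sex-linked genes and of mutated and deleted genes are given as values. A list score is the mean log2(CPM + 1) over the list's members in a tumor. Scores were compared with the exact permutation test and adjusted over the lists. The named genes are Rbl1, Rbl2, Rb1 and Trp53, and up to 12 genes in each direction with adjusted p under 0.05, a log2 fold change of at least 1 in size and at least 5 CPM in the higher group. To these come up to 4 members of each list with adjusted p under 0.05. Since fewer than 10 genes passed, the 5 genes of smallest p in each direction with at least 5 CPM were named too. For each list called by camera with fewer than 2 members past the threshold, the 2 members of smallest p in its direction were named. Unnamed gene models were passed over. Other genes were chosen after their values were seen, and this is said where they appear.

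Tumors of a mouse were compared by the mean Pearson correlation of log2(CPM + 1) over the tested genes, with a one-sided permutation of mouse labels within groups (100000 draws). The tests were checked on simulated counts with 100 genes changed by log2 1 and 100 by log2 2, and with no mouse effect. edgeR on tumors recovered 48% and 82% of these and called 9 of the unchanged genes among 14756 tested. On counts summed per mouse it recovered 27% and 71% and called 2 unchanged genes among 14857. DESeq2 1.42.0 recovered 65% and 92% and called 40 unchanged genes. With a simulated mouse effect of SD 0.5 (log2) and no group effect, edgeR on tumors called 22 genes. Counts summed per mouse and voom with the mouse as a random block called 0 each. The correlation of tumors of one mouse, estimated in voom, was 0.479 in this simulation and 0.201 in the data. The simulated mouse effect was thus stronger than that of the data, and the 22 calls do not measure false calls here.

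Tumors held 12700334 to 34620979 estimated counts. Chi-square per degree of freedom between tumors of a group ran from 36.7 to 349, so no library appeared to be deposited in duplicate within a group. Alternatives covered other scaling factors, count filters, DESeq2, voom with and without the mouse as a block, counts summed per mouse, the normalized table, Xist or Rn45s as a covariate and leaving out each tumor or mouse. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.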

Results

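The transcriptomes of 16 mouse small cell lung cancers were measured, 8 with CRISPR mutation of p107 and 8 with CRISPR mutation of p130. Both proteins are relatives of the retinoblastoma protein RB, which represses E2F target genes, and all tumors were started by deletion of Trp53 and Rb1. The p107 tumors came from 4 mice, with 13300223 to 34620979 estimated counts per tumor, and the p130 tumors from 3 mice, with 12700334 to 21254514. Depth did not differ detectably between the groups (exact permutation p = 0.253). Between 17085 and 18047 genes were detected per tumor. The ribosomal transcript Rn45s took 0.663% to 7.75% of the counts in p107 tumors and 0.547% to 4.31% in p130 tumors (exact permutation p = 0.417). The groups differed in sex-linked transcripts. Xist, the RNA that coats the inactive X chromosome of female cells, lay at 140 to 2270 CPM in the 6 tumors of p130 mice sgp130_6637 and sgp130_6638, where the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at or below 0.336 CPM. In all 8 p107 tumors and in the 2 tumors of p130 mouse sgp130_6697, Xist was at or below 4.17 CPM and Kdm5d at or above 15 CPM. Every p107 tumor therefore had a male pattern and 6 of the 8 p130 tumors a female one.

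The mutated genes were examined first. Rbl2, which encodes p130, was lower in the tumors with mutated p130, at 30.1 ± 14 CPM (SD, n = 8) against 85.1 ± 25.4 CPM (SD, n = 8) in p107 tumors, a 2.82-fold difference (95% interval 1.9 to 4.2). Each p107 tumor, the lowest at 55.4 CPM, lay above each p130 tumor, the highest at 54.4 CPM (exact permutation p = 0.000155, the smallest these splits can give). Between mice the exact permutation p was 0.0286, also the smallest possible. In the edgeR test over all genes Rbl2 did not pass (log2 fold change 1.5 ± 0.27 SE, adjusted p = 0.1). Rbl1, which encodes p107, was not lower in the tumors with mutated p107, at 122 ± 65.2 CPM (SD, n = 8) against 85.8 ± 20.7 CPM (SD, n = 8), with a log2 fold change of 0.51 ± 0.26 SE (edgeR adjusted p = 0.464). Tumors sgp107_6627T2 (247 CPM) and sgp107_6630T3 (200 CPM) held the highest Rbl1 levels. Rb1 lay at 496 ± 155 CPM in p107 and 464 ± 146 CPM in p130 tumors (SD, n = 8 each, edgeR adjusted p = 0.901), and Trp53 at 21.5 ± 3.76 CPM and 26.1 ± 7.38 CPM (SD, n = 8 each, edgeR adjusted p = 0.535). A small CRISPR insertion or deletion need not lower a transcript, and gene-level counts do not show which exons were read, so the levels of Rbl1, Rb1 and Trp53 do not check the labels.

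**Figure D1:**
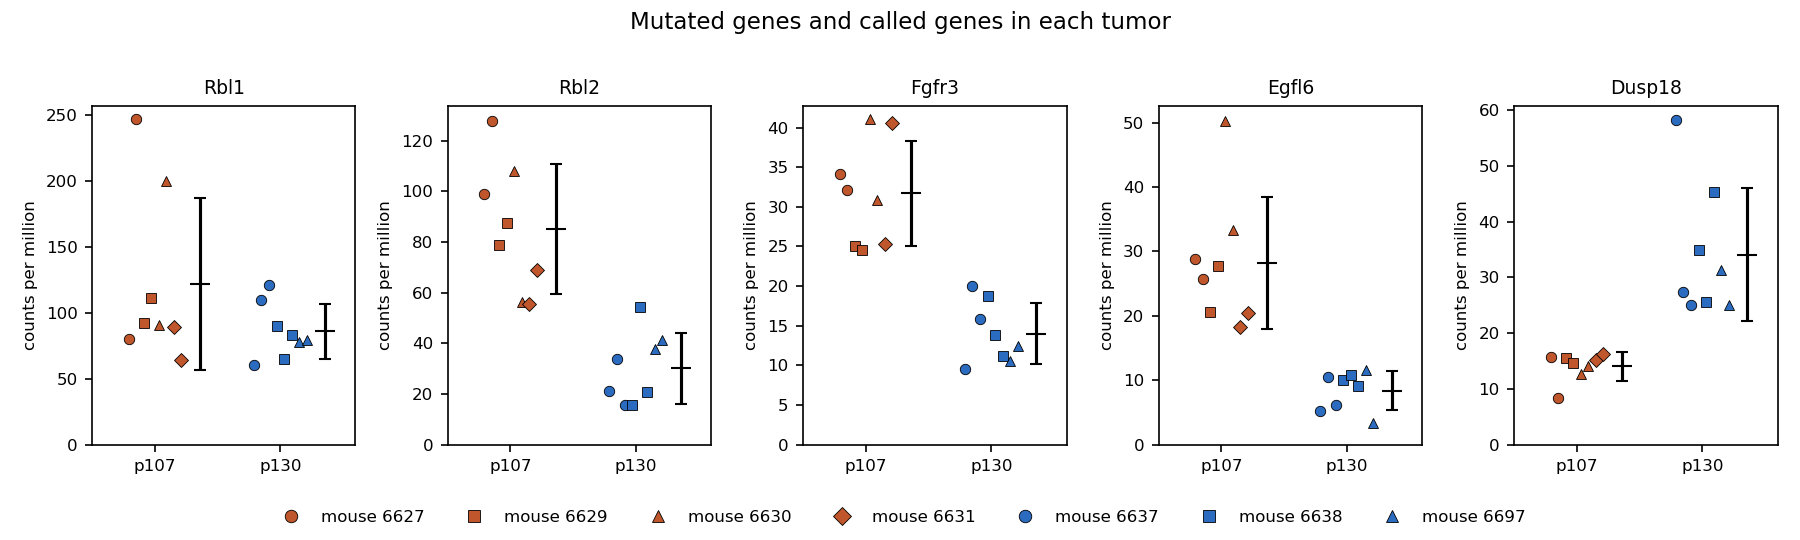
Expression in CPM (linear axis) of Rbl1, Rbl2, Fgfr3, Egfl6 and Dusp18 in each of the 8 p107 and 8 p130 tumors, with 1 symbol per mouse and black bars for the mean ± SD. All 8 p107 tumors lie above all 8 p130 tumors for Rbl2, Fgfr3 and Egfl6 and below them for Dusp18, while the groups overlap for Rbl1.

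Few genes separated p107 from p130 tumors. All 16 tumors had p107 or p130 mutated, so a difference cannot show which group changed. Likewise, a lack of difference does not show what either mutation does. Fgfr3, a fibroblast growth factor receptor, was 2.26-fold higher in p107 tumors (95% interval 1.74 to 2.94), at 31.7 ± 6.68 CPM against 14 ± 3.84 CPM (SD, n = 8 each). Egfl6, an X-linked gene for a secreted protein with EGF repeats, was 3.37-fold higher (2.28 to 4.98), at 28.2 ± 10.2 CPM against 8.36 ± 3.04 CPM. Dusp18, a dual-specificity phosphatase gene, was 2.42-fold higher in p130 tumors (1.82 to 3.23), at 34.1 ± 11.9 CPM against 14.1 ± 2.58 CPM. For each of these 3 genes all 8 tumors of one group lay beyond all 8 of the other (exact permutation p = 0.000155). The genes were selected on these same tumors, so this separation is not independent support. Mboat1, which did not pass in edgeR, separated the groups as fully (exact permutation p = 0.000155). Xist was higher in p130 tumors, at 904 ± 884 CPM against 1.39 ± 0.919 CPM (SD, n = 8 each), following the sex pattern above. These 4 were the only ones of 14857 genes tested with an edgeR adjusted p under 0.05, each at 0.0202. Without adjustment, 1756 genes had p under 0.05, 922 higher in p107 and 834 higher in p130, where 743 would be expected by chance. That expectation takes the tumors as independent. With the mouse as a random block in voom, 935 of 14857 genes had an unadjusted p under 0.05. With counts summed per mouse in edgeR, 1013 of 16267 did.

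Of the genes next in order, none passed the edgeR test. Higher in p107 tumors were Mboat1, a lysophospholipid acyltransferase gene (log2 fold change 0.87 ± 0.17 SE, adjusted p = 0.143), and the potassium channel gene Kcnb2 (1.53 ± 0.31 SE, adjusted p = 0.143). Lower in p107 tumors were Elmod1 (adjusted p = 0.1), Pde1a and Mipep (adjusted p = 0.143 each). Elmod1 lay at 0.441 ± 0.411 CPM in p107 and 12.7 ± 12 CPM in p130 tumors (SD, n = 8 each). Pde1a, a calmodulin-dependent phosphodiesterase gene, lay at 8.24 ± 4.34 CPM and 147 ± 112 CPM, and ranged from 1.19 to 279 CPM among p130 tumors. Mipep, a mitochondrial peptidase gene, lay at 13.3 ± 2.88 CPM and 23.9 ± 5.34 CPM. With counts summed per mouse, 1 gene passed in edgeR, Pde1a (adjusted p = 0.0407, with 1.84e-06 to 0.758 over its alternatives); with the mouse as a random block in voom 0 passed (935 at an unadjusted p under 0.05), against 335 with DESeq2 on tumors, and edgeR gave 0 without tumor sgp107_6630T2 (1473 unadjusted). Among the 10 tumors with Y-linked transcripts, 8 of them p107, 0 genes passed in edgeR (1037 unadjusted), with log2 fold changes of 1.46 ± 0.26 SE for Fgfr3, 1.92 ± 0.52 SE for Egfl6, -1 ± 0.23 SE for Dusp18 and -1.11 ± 0.65 SE for Xist.

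The neuroendocrine, NEUROD1-type and POU2F3-type lists of small cell lung cancer states were not called between the groups. The neuroendocrine list had 16 of 30 members higher and 14 lower in p107 tumors, and its score was 7.53 ± 0.131 in p107 and 7.53 ± 0.167 in p130 tumors (SD, n = 8 each, exact permutation p = 0.938). The list of NEUROD1-type neuronal genes had 11 of 16 members higher in edgeR but 5 of 16 in voom (mean log2 fold change -0.17 in voom, exact permutation p = 0.904) and that of POU2F3-type tuft cell genes 8 of 10 (score 3.001 ± 0.276 against 2.65 ± 0.193, SD, n = 8 each, exact permutation p = 0.0109, adjusted p = 0.158). Pou2f3 itself, chosen after its values were seen, stayed at or below 0.278 CPM in each tumor. E2F targets of the G1/S phase, on which p107 and p130 act, had 32 of 43 members higher and 11 lower in p107 tumors, with scores of 6.74 ± 0.264 and 6.69 ± 0.161 (SD, n = 8 each, exact permutation p = 0.666). The G2/M list had 15 of 40 members higher (exact permutation p = 0.780). Lists of cell cycle inhibitors and cyclin D genes (12 of 23 higher, mean log2 fold change 0.02 but ranked lower by camera, exact permutation p = 0.844), p53 targets (10 of 20, p = 0.705) and MYC family and Nfib genes (8 of 14, p = 0.415) did not pass either. None of these 8 lists was called by camera, and 0 of their members passed over all genes tested. Adjusted over the list alone, Bcl2 in the MYC family and Nfib list passed (edgeR adjusted p = 0.0177).

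Among 33 lists, camera with its preset correlation called 6. Higher in p107 tumors were the endothelial list, with 16 of 18 members higher (mean log2 fold change 0.36, adjusted p = 6.76e-06), and the list of NOTCH, REST and YAP genes of non-neuroendocrine cells, with 16 of 19 (0.47, adjusted p = 1.35e-05). The ribosome biogenesis list was lower, with 28 of 30 members lower in edgeR and 29 in voom (-0.21, adjusted p = 1.27e-05). A list of genes of epithelial-mesenchymal transition and matrix remodelling, called the matrix remodelling list below, had 21 of 24 members higher in edgeR and 19 in voom. This list and those of B and plasma cells (9 of 10) and mesothelium (7 of 7) were higher at a camera adjusted p of 0.0218 each. With an estimated correlation no call held, with adjusted p = 0.475 for 5 of these lists and adjusted p = 0.638 for the B and plasma cell list. The scores did not pass either. The lowest adjusted p of 33 lists in the exact permutation test was 0.158, with 8 lists at an unadjusted p under 0.05.

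Members of these 6 lists did not pass over all genes tested, and are given as values. In the NOTCH list, the receptor genes Notch1 and Notch2 lay at 23.7 ± 15.9 CPM and 32.9 ± 7.34 CPM in p107 against 8.63 ± 3.34 CPM and 19.4 ± 6.75 CPM in p130 tumors (SD, n = 8 each), and 3 members passed when adjusted over the list alone. In the endothelial list, 6 members passed when adjusted over the list alone; VE-cadherin (Cdh5) lay at 39.2 ± 9.24 CPM against 27.2 ± 4.85 CPM and Tie1 at 12.5 ± 3.93 CPM against 7.97 ± 2.40 CPM. The nucleolar genes Mybbp1a (107.2 ± 6.44 CPM against 147 ± 26.3 CPM) and Ddx21 (105 ± 15.2 CPM against 148 ± 35.1 CPM) led the ribosome biogenesis list, where 2 members passed when adjusted over the list alone. In the matrix list, Tgfbi lay at 33.5 ± 19 CPM against 18 ± 6.82 CPM; Zeb2 had a mean of 66.1 CPM against 21.1 CPM, but its log2 fold change was 0.14 without mouse sgp107_6627, and 0 members passed over the list alone. In the B and plasma cell list, 3 members passed over the list alone. Sdc1, which epithelial cells also make, lay at 131 ± 33.9 CPM against 76.5 ± 17.1 CPM. The B cell receptor gene Cd79b reached 9.90 CPM in tumor sgp107_6631T2 and was at or below 2.14 CPM in the other tumors; without mouse sgp107_6631 the mean log2 fold change of this list was 0.17 and camera did not call it (adjusted p = 0.195). In the mesothelium list, Rspo1 lay at 10.5 ± 10.8 CPM against 2.02 ± 1.21 CPM and Msln at 16.3 ± 13.4 CPM against 7.48 ± 5.16 CPM, and 1 member passed over the list alone. Of 15 lists of other cell types, the endothelial, B cell and mesothelium lists among them, 14 had a higher mean score in p107 tumors, a tally that was not tested.

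**Figure D2:**
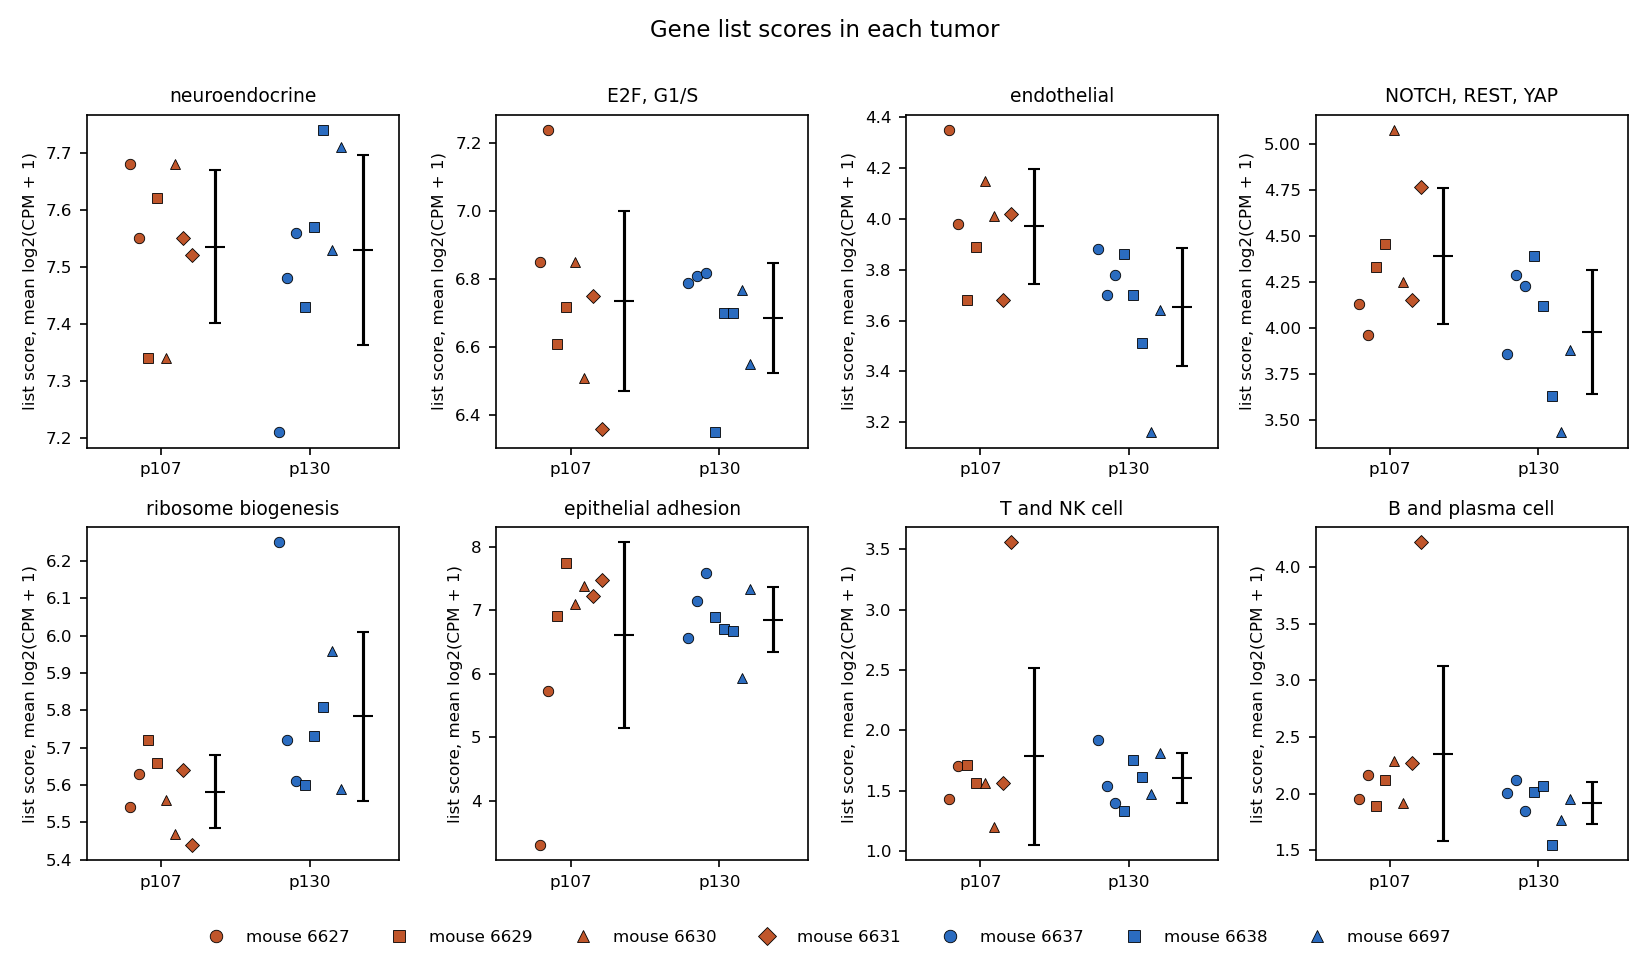
List scores, the mean log2(CPM + 1) over list members, of 8 gene lists in each of the 8 p107 and 8 p130 tumors, with 1 symbol per mouse and black bars for the mean ± SD; each vertical axis has its own range and does not start at 0. The groups overlap in all 8 lists, tumor sgp107_6627T1 has the lowest epithelial adhesion score (3.31) and tumor sgp107_6631T2 the highest B and plasma cell score (4.22).

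The other lists were not called by camera, and their exact permutation p given here are unadjusted. In the hepatocyte list only 3 of 14 members were tested (exact permutation adjusted p = 0.158). In the cardiac and skeletal muscle list only 4 of 15 were tested. Those higher in p107 tumors, with their exact permutation p, were pericyte and smooth muscle (0.111), fibroblast (0.346), macrophage (0.341), neutrophil (0.445, though 4 of 7 members were lower), T and NK cell (0.768), alveolar type 1 (0.342) and type 2 (0.430), airway epithelium (0.396), red blood cell (0.0661), hepatocyte (0.0334), cardiac and skeletal muscle (0.709) and antigen presentation (0.589). Schwann cell and glia (0.830), oxidative phosphorylation (0.606), hypoxia and glycolysis (0.901), unfolded protein response (0.228), immediate early genes (0.637) and epithelial adhesion (0.765) had lower mean scores, and interferon genes 3.71 against 3.70 (0.976). Adjusted over the list alone, 4 of the 5 tested red blood cell genes, 2 fibroblast and 2 airway genes passed, and 0 genes of the other lists named here. The red blood cell score was 4.3 and 4.59 in the tumors of mouse sgp107_6631 and 3.09 in sgp107_6627T1, and 1.16 to 2.08 in the other 5 p107 tumors, within the 0.99 to 2.25 of p130 tumors. Over all genes tested, 0 genes of the 33 lists tested passed; Xist belongs to the list of sex-linked genes, which is given as values.

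Tumors that shared a mouse resembled each other. The mean correlation of gene levels was 0.946 between tumors of one mouse and 0.926 between tumors of different mice of the same group, a difference of 0.0201 (one-sided permutation p = 0.00489). The 16 tumors were therefore not fully independent samples, and the tests on tumors treat them as if they were.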

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

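All tests in this part were chosen only after the result was seen. A tumor is named here when its distance from the nearest of the other tumors is a large share of its group's range (Dixon's ratio, groups of 8). Of 122 groups of values examined, 10 held such a tumor, and chance gives about 1 in 20, or 6.1.

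The first pattern is the 4 genes that separated the groups. Of 100 splits of the 16 tumors into 8 and 8, 1 gave 4 genes, the real one (highest other 0). This would argue against chance only if tumors were independent, and tumors of one mouse resembled each other. The other splits could divide the tumors of a mouse, unlike the real one, so they cannot decide. With the tumors of a mouse kept together, 4 of 35 splits gave as many (highest other 199), with counts summed per mouse 3 of 35 reached the real 1 gene (highest other 5), and with DESeq2 6 of 35 reached 335 (highest other 1300), so chance is not excluded at the level of mice. The split with 199 genes, mice sgp107_6627, sgp130_6637 and sgp130_6697 against the rest, points to a structure of the samples. On the first principal component of log2(CPM + 1), with 30.1% of the variance, sgp107_6627T1 (-111.3), sgp107_6627T2 (-45.7), sgp130_6697T1 (-45) and sgp130_6637T1 (-27) were lowest. The remaining tumors lay from -1.8 to 43.3, the other tumors of these mice among them. Single tumors of both groups could thus carry this structure, which was not tested. Sex accounts for Xist, with a log2 fold change of -1.11 ± 0.65 SE among tumors with Y-linked transcripts, but stays open for Fgfr3, Egfl6 and Dusp18: 3 of 3 kept their direction there by over 2 SE, yet they were selected on these same tumors and only 1 p130 mouse has Y-linked transcripts. The mutation of p107 or p130 stays open too, as untested apart from the mice.

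The second pattern is the set of lists called by camera. The preset correlation gave 6 or more lists in 79 of 100 splits of the tumors (highest other 17) and in 26 of 35 splits of the mice (highest other 15), so chance cannot be excluded for any of the 6 calls. A larger share of other cells in p107 tumors may also raise the endothelial and NOTCH lists. The mean score of 8 other cell type lists was 0.21 higher in p107 tumors (exact permutation p = 0.176), and the endothelial score exceeded that mean by a further 0.106 (exact permutation p = 0.546). Neither value decides, and the NOTCH genes could belong to tumor cells or to other cells.

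The third pattern is tumor sgp107_6627T1. Its epithelial adhesion score was 3.31, against 5.73 to 7.74 in the other p107 tumors, with Cdh1 at 26.3 CPM, Epcam at 28.6 CPM and Krt8 at 14 CPM. Its Zeb2 level was 355 CPM against 15 to 34.9 CPM, and Tie1 was 21.6 CPM against 8.04 to 12.6 CPM. Dilution by other cells would lower all tumor cell genes and is argued against by its neuroendocrine list score of 7.68, which lay 1.27 SD above the mean of the other p107 tumors. Loss of epithelial genes in tumor cells is a candidate explanation that the design does not test.

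Further tumors are given as values. Tumor sgp107_6631T2 had a T and NK cell score of 3.56 against 1.2 to 1.71 in the other p107 tumors, a B and plasma cell score of 4.22 against 1.89 to 2.29, and Cd79b at 9.90 CPM against 1.16 to 2.14 CPM. Tumor sgp107_6627T2 had a fibroblast score of 4.67 against 3.52 to 3.93 and Dusp18 at 8.33 CPM against 12.7 to 16.3 CPM. Among p130 tumors, sgp130_6637T1 had an oxidative phosphorylation score of 7.36 against 6.47 to 6.82, and sgp130_6697T2 a POU2F3-type tuft cell score of 3.05 against 2.47 to 2.74.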

How the results depend on the processing

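The covariate for Rn45s, the fit on tumors with Y-linked transcripts and the fit without tumors sgp107_6627T1 and sgp107_6631T2 were chosen after seeing the data. The count of 4 genes was 4 with other scaling factors, the stricter filter, a non-robust fit, Rn45s left out, a minimum fold change or an adjusted p under 0.10, and 5 without a filter. It was 335 with DESeq2, 7 with voom without a block, 1 with counts summed per mouse, 0 with voom and the mouse as a random block (935 at an unadjusted p under 0.05), 0 with limma on the normalized table (1460), 0 in edgeR with Xist as a covariate (1043), 0 in edgeR on tumors with Y-linked transcripts (1037), 7 without sgp107_6627T1 and sgp107_6631T2 (3 shared) and 1 with the Rn45s covariate. The normalized table lacks Xist and Egfl6, and the fits per mouse and on tumors with Y-linked transcripts use fewer samples; otherwise the cause was not tested. Leaving out each tumor or mouse gave 0 to 10 genes: 0 without tumor sgp107_6630T2 or mouse sgp107_6629, sgp107_6631, sgp130_6637 or sgp130_6638, 1 without tumor sgp130_6638T5 or mouse sgp107_6627, 2 without tumor sgp107_6629T2, sgp107_6631T2, sgp130_6637T1 or sgp130_6638T3, and 10 without mouse sgp130_6697, where Y-linked genes entered. Fgfr3, Egfl6 and Dusp18 kept their direction in all alternatives, with adjusted p up to 0.417, 0.570 and 0.393. Rbl2 passed with DESeq2 (1.51), voom without a block (1.55) and without tumor sgp130_6638T4 (1.68). When tumors or mice were left out, Rbl2 ran from 1.33 to 1.68 and Rbl1 from 0.28 to 0.67. Over the other alternatives Rbl2 ran from 1.11 to 1.56, with adjusted p up to 0.69. Rb1 turned sign without mouse sgp107_6630 (-0.04) and Trp53 with the Xist covariate (0.11), neither past the threshold. The count of 6 lists was 0 with an estimated correlation and 0 with fry (lowest adjusted p 0.256), 6 to 9 in the other fits (the B and plasma cell list was lost on tumors with Y-linked transcripts, adjusted p = 0.051, with the Xist covariate, 0.214, and without sgp107_6627T1 and sgp107_6631T2, 0.117), and 3 (without mouse sgp130_6697) to 12 (without mouse sgp130_6637) when tumors or mice were left out; it was 10 without mouse sgp107_6627 or tumor sgp130_6638T4. The endothelial, NOTCH and ribosome biogenesis lists were called in all 23 of these fits, and the other 3 lost the call in 5 each: matrix remodelling without mouse sgp130_6638 or sgp130_6697 or tumor sgp107_6630T2, sgp130_6638T5 or sgp130_6697T2 (adjusted p 0.0506 to 0.155), B and plasma cells without mouse sgp107_6631, sgp130_6638 or sgp130_6697 or tumor sgp107_6631T2 or sgp130_6638T5 (0.0612 to 0.195), and mesothelium without mouse sgp107_6629, sgp130_6638 or sgp130_6697 or tumor sgp107_6629T2 or sgp130_6697T1 (0.0536 to 0.204). No list score passed in any setting, and the mouse similarity kept its direction with Spearman correlation (permutation p = 0.0071) and over the most variable genes (permutation p = 0.00586). No paired analysis was possible because each mouse carried 1 genotype. Depth limits genes with few counts, which the filter left out of the 14857 tested.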

Other observations

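The tests of the Nfib, Mycl1 and Myc regions and relations below were written down before their results were seen, but the tumors that prompted them were picked from the data; the genes named here were chosen after their values were seen.

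Single tumors of both groups had high levels of Mycl1 and Nfib, oncogenes of small cell lung cancer. Mycl1, a MYC family gene, lay at 769 CPM in p130 tumor sgp130_6638T4, 594 CPM in p130 tumor sgp130_6697T1, 513 CPM in p107 tumor sgp107_6627T2 and 426 CPM in p107 tumor sgp107_6629T2, against 58.0 to 234 CPM in the other tumors. Nfib, a transcription factor gene, lay at 4230 CPM in sgp130_6697T1, 1740 CPM in sgp107_6627T1 and 1180 CPM in sgp107_6627T2, against 171 to 464 CPM in the others. Between the groups neither passed (Mycl1 log2 fold change -0.71 ± 0.57 SE, edgeR adjusted p = 0.649; Nfib -0.43 ± 0.69 SE, adjusted p = 0.838). Myc was highest at 41.2 CPM in p130 tumor sgp130_6637T1, which also had the highest Neurod1 level (9.15 CPM) and the highest ribosome biogenesis score (6.25). Mycn reached 31.4 CPM in sgp107_6630T2. Its mean was higher in p107 tumors, at 15.9 ± 9.05 CPM against 5.85 ± 4.61 CPM in p130 tumors (SD, n = 8 each). It did not pass (log2 fold change 1.44 ± 0.48 SE, edgeR adjusted p = 0.273).

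A gain of the chromosome region may raise Mycl1 together with its neighbors. For each tumor, the median deviation of the 10 nearest expressed genes from their levels over all tumors was set against 10631 windows of the same kind, in the gene order of GRCm38. In sgp130_6638T4, sgp107_6627T2 and sgp107_6629T2 the Mycl1 neighbors lay at the 99.8 percentile each, with medians of 1.63, 0.93 and 0.73 (log2) and 7 of 10 genes above their usual level in each. Cap1 deviated by 1.88, 1.69 and 1.19 in these tumors, Trit1 by 3.01, 2.04 and 0.86, and Ppie by 2.93, 1.11 and 1.13, while Zmpste24 deviated by -0.12, -0.22 and -0.12 and Rlf by -0.12, -0.06 and -0.20. In sgp130_6697T1 the median was 0.33, at the 93.9 percentile, which does not decide. For Nfib, the neighbors in sgp130_6697T1 lay at the 99.9 percentile, with a median of 1.83 and all 10 above their usual level, Mpdz by 3.98 and Zdhhc21 by 2.35. In sgp107_6627T1 and sgp107_6627T2 they lay at the 19.5 and 15 percentiles, which argues against a gain that spans all 10 neighbors. Ptprd (3.71 and 0.82) and Mpdz (1.11 and 1.07) were raised there while Rasef was low (-5.04 and -1.02), so a smaller gain stays open. High neighbors also occurred where the gene itself lay below its level in the tumors named above. The Nfib neighbors of sgp130_6697T2 lay at the 99.8 percentile (median 0.78, 8 of 10 above), with Nfib at 464 CPM, a deviation of 0.36. The Mycl1 neighbors of sgp130_6697T2 and sgp130_6637T3 lay at the 97.9 and 96.9 percentiles. Mycl1 itself was at 234 and 161 CPM there, deviations of 0.66 and 0.12. In sgp130_6697T2 both genes were at the top of the range of the tumors without a high level. Gains around Mycl1 in 3 tumors and around Nfib in sgp130_6697T1 may therefore be proposed only as a hypothesis, since DNA was not analysed here and shared regulation of neighbors was not tested.

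The 3 tumors with the highest Nfib also had the 3 lowest epithelial adhesion scores, 3.31 in sgp107_6627T1, 5.73 in sgp107_6627T2 and 5.93 in sgp130_6697T1. A graded relation may underlie this, but over the other 13 tumors Nfib and the score had r = 0.150 (permutation p = 0.623) and rho = 0.159 (permutation p = 0.603), and r = -0.00778 without the 2 tumors of most extreme Nfib. For Myc and the ribosome biogenesis score, over the 15 tumors other than sgp130_6637T1, r was -0.150 (permutation p = 0.599) and rho -0.155 (permutation p = 0.578), and r was -0.225 without 2 tumors. Within groups the r values were 0.176 and -0.138. Adjusted over these 2 relations, both p were 0.623, and neither graded relation was found in these tumors. They covered only 171 to 464 CPM of Nfib and 3.91 to 16.3 CPM of Myc, so a relation at higher levels stays open.

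Tumor sgp107_6627T1 was unlike the rest in further genes. Calca lay at 117 CPM against 1200 to 7920 CPM in the other 15 tumors. Stmn2 (231 CPM), Dcx (535 CPM), Nmu (124 CPM), Gfap (80.8 CPM) and Vim (289 CPM) were at their highest there, while Chga was 576 CPM. Across genes, its closest tumor was sgp107_6627T2 of the same mouse (r = 0.915), against r of 0.809 to 0.894 with tumors of other mice. In tumor sgp107_6631T2, with the high lymphocyte scores, B2m reached 1880 CPM, H2-K1 1450 CPM and Cd8a 26.8 CPM, each the highest of the 16 tumors. The club cell gene Scgb1a1 ran from 55.4 CPM in sgp130_6697T1 to 7710 CPM in sgp107_6630T2. The Y-linked gene Ddx3y lay at 9.74 CPM in sgp107_6629T2 against 72.0 to 110 CPM in the other 9 tumors with Y-linked transcripts, while Eif2s3y was 66.0 CPM and Uty 36.4 CPM there.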
